A study of Rattus norvegicus with 4 samples.

How the data were processed

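Total RNA of 4 NR8383 cultures exposed to NRCWE055 was measured on 1-colour Agilent arrays with Cy3-labelled cRNA, 1 array per culture. The 4 arrays lay on 1 slide and were read in 1 scan, so slide and scan could not be tested as batches. Samples were put in 1 group by their titles. The source names of replicates 2, 3 and 4 carry other nanotube numbers than their titles and treatment entries do, and the titles were followed. No sample of unexposed cells was analysed here, so no comparison between groups was made. The study design calls the samples biological replicates.

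The deposited files hold a row per spot from Agilent Feature Extraction 11.0.1.1, per the file headers and the submitters' processing notes. The processed signal is an intensity that, per the file headers, was background-subtracted and detrended within each array, and it had not been normalized between arrays. The other columns used were the raw median intensity of each spot and of its local background, as deposited, and deposited flags of 0 or 1 for detection, saturation and outlier spots. The deposited background-subtracted signal of each spot was used only in a check for uneven signal within spots. The raw mean spot signal was not used here, so the alternative background correction started from the raw median signal.

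Control spots were left out, which left 58717 spots of 45598 probes, and spots marked as outliers (427 to 714 per array) were dropped. The log2 processed signal was averaged over the spots of a probe. A probe counted as detected on an array when most of its usable spots were well above background. Between 18585 and 19931 probes (40.8% to 43.7%) were detected per array. Because this was under 50% of the probes, each array was scaled by subtracting its 75th percentile over the 17807 probes detected on all arrays. The plan had named the 75th percentile without naming the probes, so this set was chosen after detection had been counted. Signal over background set what could be measured. The lowest detected level was between -7.49 and -6.81 on the log2 scale, and 1 to 3 of 308 negative control spots per array were well above background.

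Probes were named by their RefSeq accession, without version, through a table of rat genes of assembly GRCr8. A symbol was found for 21109 probes (46.3%), covering 16581 genes, and 24489 probes stayed without one, of which 6994 were detected on all arrays. The array was designed on another genome build, so no coordinates are given. A gene's level was the mean of its detected probes, and a gene was not above background only if none of its probes was. Of 3658 genes with several probes, 797 had probes that disagreed on detection. The probes of the 1712 genes with several detected probes spanned a median of 1.94 on the log2 scale. Names in the lists were updated for 3 old symbols.

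Before the data were examined, 25 gene lists were fixed, 18 for macrophages, cell processes and reference genes and 7 for other cell types, with 431 distinct genes, together with the tests and most alternatives. The genes named were fixed by the same rule. They were 81 list members chosen whatever their values, the 10 detected genes with the largest SD, up to 10 genes with only saturated probes, and the members of any list that varied past its test. The last 2 parts of the rule named no gene, and a few of the fixed list members are not reported here.

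Spread was the SD over the 4 arrays. Each list with at least 5 detected members was tested by a one-sided permutation test of its median SD against 10000 random lists of the same size, matched on mean level in 20 bins. Probes printed several times per array were tested with limma 3.58.1 in R 4.3.3, using the moderated F test over replicate spots with the array as a factor. Benjamini-Hochberg adjustment with a threshold of 0.05 was used for the list test and for the test over replicate spots. No other test was adjusted. Detection shares were compared with Fisher's exact test. Files were read with version 1.17.8 of the data.table package and figures drawn with matplotlib 3.10.9 in Python 3.11.15.

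Both tests were checked on simulated data. For the comparison of arrays over 1742 probes, changes of 0.1, 0.25, 0.5 and 1 on the log2 scale were recovered in 14%, 72%, 92% and 90% of 50 probes each, with 5 false calls among 1542 unchanged probes. The list test, run 20 times on 8685 genes with 2000 random lists, made 2 calls among 360 unchanged lists. Simulated genes varied independently of one another. Shifts between arrays that genes share were not simulated, so this rate need not hold for the measured lists.

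Alternatives were normexp correction with an offset of 50, centring on the median, quantile normalization, a looser detection flag, detection on at least 3 arrays, the brightest probe per gene, keeping outlier spots, no filter on dim probes, and leaving out each replicate. Scaling to the 75th percentile of all spots and matching lists on the 50 nearest genes in level were added after the data had been seen.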

Results

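Gene expression was measured in NR8383 cells, a rat alveolar macrophage line first grown from lung lavage fluid. The cells had been exposed for 4 h to NRCWE055, a pristine single-walled carbon nanotube, at 11 cm2 of nanotube surface per cm2 of culture, and were described as being at 20 passages. The 4 samples analysed here formed 1 exposed group, and the study design describes them as biological replicates. Unexposed cells belong to the study design but were not analysed here, so no value below is a response to the nanotubes. The data describe which genes were measurable in exposed cells and how closely 4 exposed cultures resembled one another.

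In exposed cells, 8685 of 16581 named genes (52.4%) were well above background on all 4 arrays. A further 1001 genes were detected on some arrays and 6895 on none. Each array detected between 8932 and 9311 genes. The 75th percentile signal of the probes detected on all arrays was 1756 for replicate 1, 2631 for replicate 2, 2861 for replicate 3 and 1873 for replicate 4. No gene had only saturated probes. The number of arrays, 4, limits the precision of every level.

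Levels are given as log2 relative to each array's 75th percentile, as mean ± SD over the 4 arrays (n = 4). They describe the probes of a gene and are not compared between genes. Of the 404 listed genes with a probe, 275 were detected on all arrays.

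Macrophage identity genes were largely detected, with 18 of 24 measured members above background on every array. Cd68, a lysosomal membrane glycoprotein of macrophages, was at 3.07 ± 0.10. Csf1r, the receptor for macrophage colony-stimulating factor, was at -1.54 ± 0.16, and the myeloid transcription factor Spi1 was at 0.82 ± 0.07. Adgre1, Cebpa, Marco and the C1q chains C1qa, C1qb and C1qc were not well above background on any array. The alveolar macrophage programme was detected for 12 of 13 members. Pparg, a nuclear receptor needed for alveolar macrophage development, was at 3.32 ± 0.12, and the fatty acid binding protein gene Fabp4 was at -1.37 ± 0.05. Car4 was not well above background.

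Markers of other cell types were mostly below detection, with 18 of 85 measured members (21.2%) above background on all arrays. The corresponding share for the macrophage identity and alveolar programme lists together was 30 of 37 (81.1%), an odds ratio of 15.5 (95% confidence interval 5.56 to 49.0, Fisher's exact test, two-sided, p = 6.174e-10). Genes are not independent replicates, so this test describes the lists on these arrays. Sftpc, Epcam and Cdh1 of lung epithelium, Col3a1 of fibroblasts, Cd3e and Cd8a of T cells, S100a9 of neutrophils, Cpa3 of mast cells and Alas2 of erythroid cells were not well above background on any array. Col1a1 was detected on 1 array, and Dcn and Kdr on 2 arrays each. With a looser detection flag Dcn was above background on 4 arrays and Sftpc, Kdr and Cpa3 on 3. Pecam1, an adhesion molecule also found on leukocytes, was at -0.89 ± 0.14. Cdh5 was at -5.49 ± 0.24, the T cell kinase gene Lck at -4.10 ± 0.04 and S100a8 at -4.90 ± 0.12. Other markers of these lists, named after their values were seen, were Fcrla at 1.26 ± 0.08 and Pax5 at -2.91 ± 0.35 of B cells, Camp at 0.45 ± 0.04 and Cxcr1 at -2.23 ± 0.05 of neutrophils, Vwf at -1.32 ± 0.12 of endothelium and Epor at -1.83 ± 0.05 of erythroid cells.

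**Figure D1:**
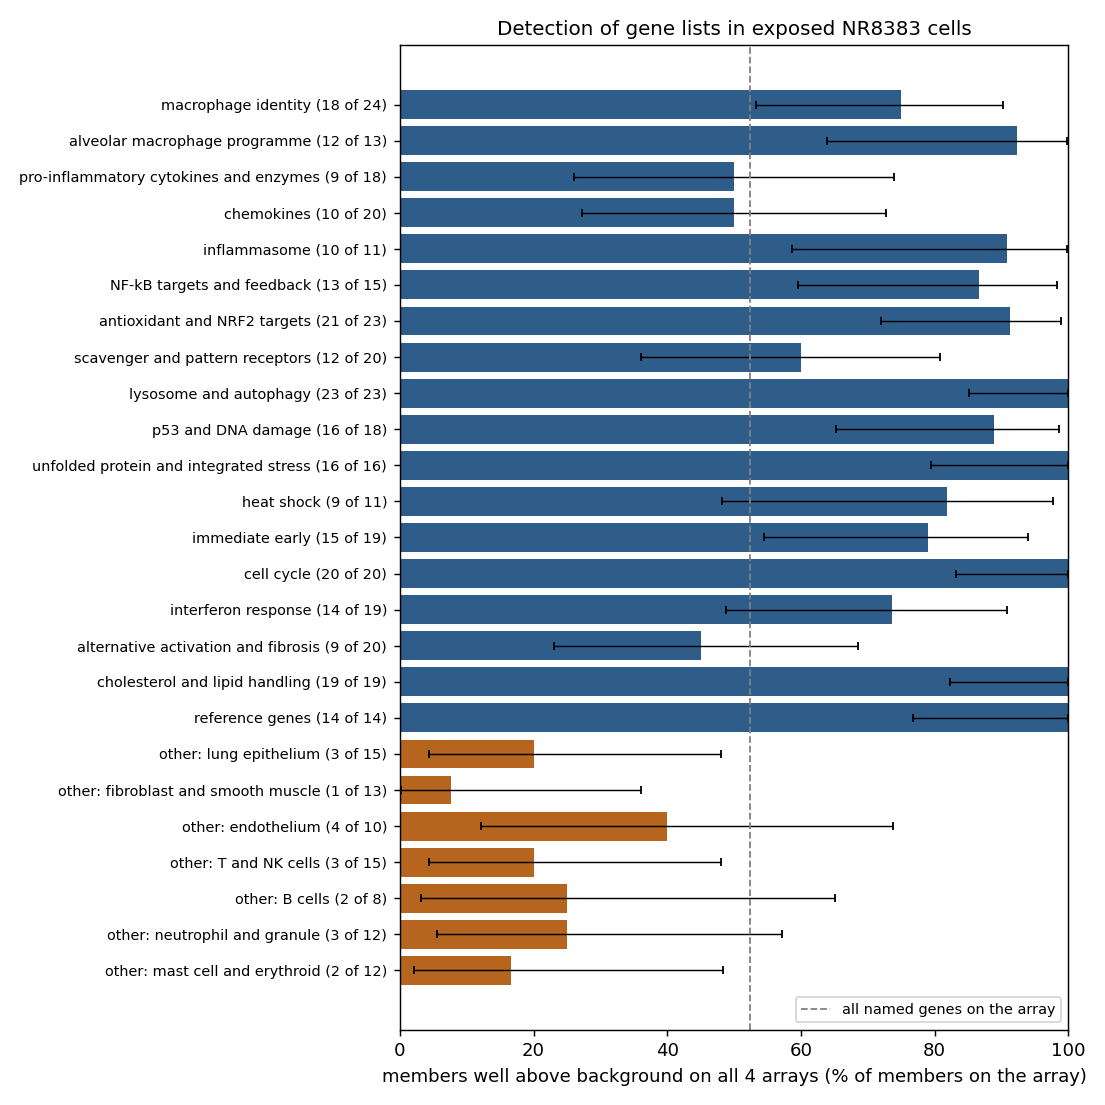
Share of the measured members of each gene list that was well above background on all 4 arrays, in percent, with exact 95% binomial intervals as error bars. Blue bars are macrophage and process lists, brown bars are markers of other cell types, and the dashed line marks the 52.4% of all named genes on the array.

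Inflammatory mediators were detected at about the share of all named genes. Among pro-inflammatory cytokines and enzymes, 9 of 18 members were above background on all arrays. Il1b was at 1.22 ± 0.07, Il1a at -0.78 ± 0.08 and Tnf at -0.86 ± 0.05, although the pair of Tnf probes lay 5.47 apart. Il6 and Ptgs2, the gene of inducible cyclooxygenase, were not well above background on any array, and Nos2 was detected on 2 arrays. Of 20 measured chemokine genes, 10 were detected. Ccl3 was at 4.28 ± 0.07, Ccl2 at -0.29 ± 0.05, Ccl4 at 0.09 ± 0.09 and Cxcl2 at 0.37 ± 0.07, whereas Cxcl1 was not well above background. With a looser detection flag, Cxcl1 and Nos2 were above background on all 4 arrays.

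Inflammasome components were detected for 10 of 11 members. The sensor gene Nlrp3 was at -4.26 ± 0.06, its 3 probes spanning 2.22, the adaptor gene Pycard at -0.46 ± 0.02 and Casp1, which encodes the protease that matures interleukin 1 beta, at -3.20 ± 0.19. Targets and feedback regulators of NF-kB were detected for 13 of 15 members, with the inhibitor gene Nfkbia at 0.44 ± 0.06 and the mitochondrial superoxide dismutase gene Sod2 at 0.74 ± 0.04. No probe was matched to Tnfaip3. In the interferon response list 14 of 19 members were detected, with Isg15 at -2.26 ± 0.18, Mx1 at -4.75 ± 0.09 and Irf7 at -2.63 ± 0.02.

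Antioxidant genes and targets of NRF2 were detected for 21 of 23 members. Hmox1, which encodes the inducible haem oxygenase, was at 3.25 ± 0.05, Srxn1 at 2.39 ± 0.08 and Nqo1 at -2.66 ± 0.11. Gclm was not well above background. Stress genes of the unfolded protein and integrated stress responses were detected for 16 of 16 members, with Atf3 at -0.04 ± 0.11, Ddit3 at 0.92 ± 0.06 and the chaperone gene Hspa5 at 2.14 ± 0.10. The heat shock list had 9 of 11 members detected. Hspb1 was at -5.34 ± 0.23 and Hspa1a was not well above background, with no probe matched to its near-identical neighbour Hspa1b.

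All 23 measured lysosome and autophagy genes were detected. Lamp1 was at 1.75 ± 0.05, the lysosomal protease gene Ctsd at 5.97 ± 0.25 and the autophagy receptor gene Sqstm1 at 2.33 ± 0.05, its 3 probes spanning 2.39. Scavenger and pattern receptors were detected for 12 of 20 members. Tlr2 was at 0.36 ± 0.11 and Tlr4 at -3.41 ± 0.11. Cd36 was at -0.96 ± 0.09, with its pair of probes 5.08 apart, and Msr1 was not well above background. Alternative activation and fibrosis genes were detected for 9 of 20 members. Arg1 was at -1.53 ± 0.15, Mmp12 at -4.28 ± 0.35 and Tgfb1 at 0.47 ± 0.11, and Spp1 was not well above background.

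Proliferation genes were detected throughout, with 20 of 20 measured cell cycle members above background. Mki67 was at -2.20 ± 0.09, its 4 probes spanning 4.21, and Ccnb1 was at 0.38 ± 0.05. No probe was matched to Top2a. Genes of p53 signalling and DNA damage were detected for 16 of 18 members. Mdm2 was at -2.38 ± 0.04, Gadd45a at -1.51 ± 0.06 and Cdkn1a at -1.59 ± 0.04, with the pair of Cdkn1a probes 6.41 apart. Immediate early genes were detected for 15 of 19 members, with Fos at -5.50 ± 0.25 and Egr1 at -5.33 ± 0.21. All 19 cholesterol and lipid handling genes were detected, with the lipid exporter gene Abca1 at -4.47 ± 0.13. The 14 measured reference genes were all detected, among them Actb at 5.81 ± 0.11, Gapdh at 5.02 ± 0.10 and Hprt1 at 0.17 ± 0.05. The 8 Gapdh probes spanned 2.70 and the pair of Hprt1 probes 1.73.

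Gene levels in the 4 exposed cultures were close to one another. The median SD between arrays was 0.0926 on the log2 scale, equal to 1.07-fold, and 96 of 8685 genes (1.11%) spanned over 2-fold. At the median SD, the mean of 4 arrays had a 95% confidence interval of ± 0.15 on the log2 scale. Correlations between arrays across genes ranged from 0.996 to 0.998, and genes are not independent replicates. The 10 genes with the largest SD were Tsks (1.58), Gpr162 (1.15), Pdzd7 (1.09), Cited2 (1.02), Gpha2 (0.93), Keap1 (0.91), Or4f61b (0.91), Prlh (0.88), Zfp3 (0.87) and Doxl1 (0.86). Keap1 encodes the repressor of NRF2, and Cited2 encodes a transcriptional coregulator. Without replicate 1 the number of genes spanning over 2-fold was 44, and from median signals with normexp correction, in place of the processed signals, it was 21. It was 163 with detection on at least 3 arrays, 777 with the looser flag and 2485 with no filter on dim probes, where the median SD was 0.244, so the closeness holds for genes well above background.

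**Figure D2:**
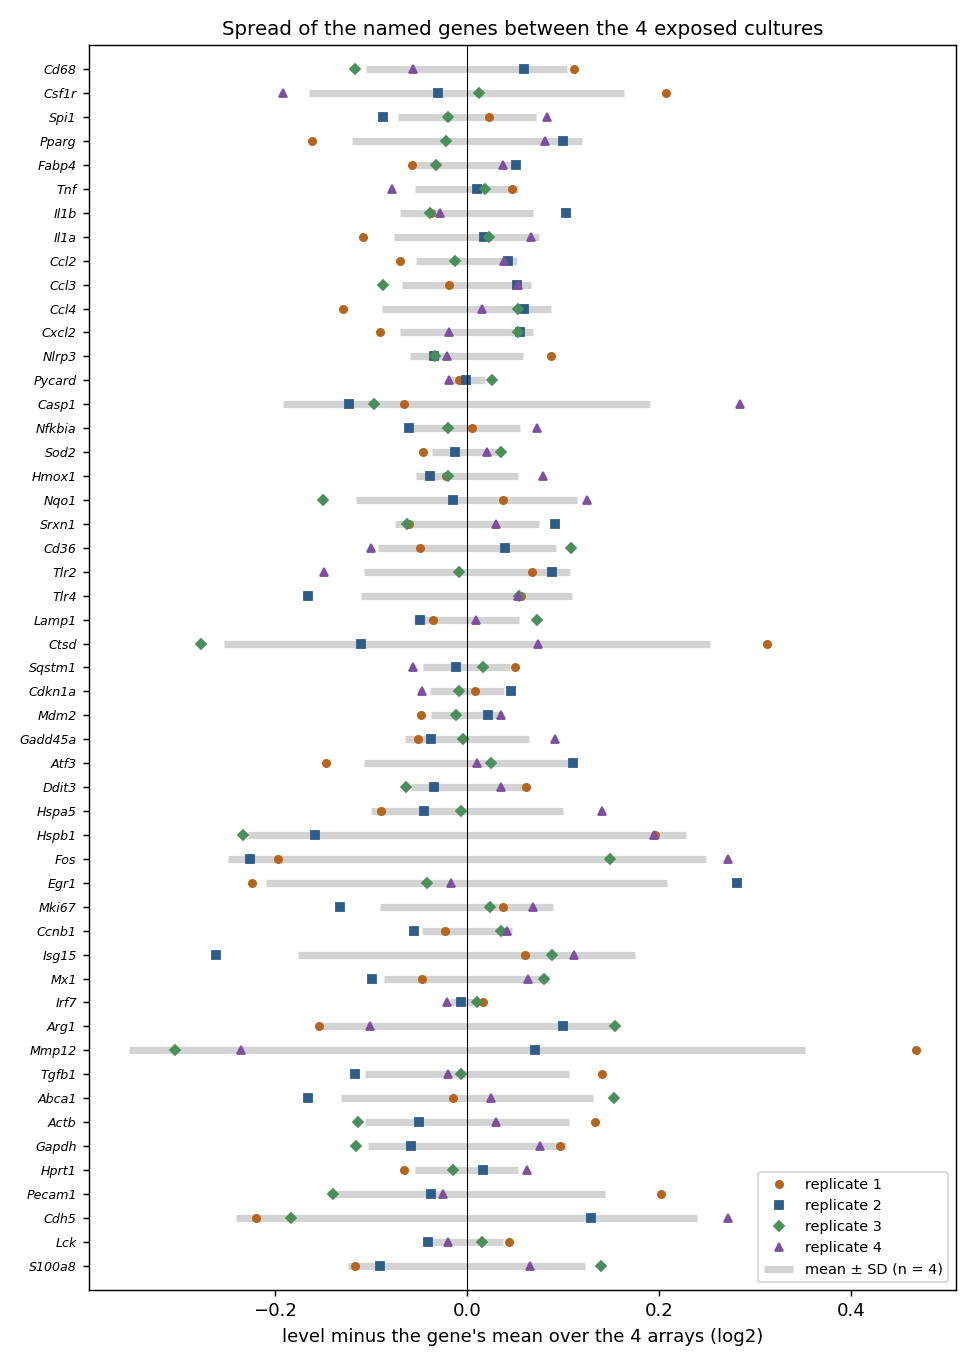
Level of the detected named genes reported here on each array minus its mean over the 4 arrays, on the log2 scale, with symbols for the 4 replicates and grey bars for ± SD (n = 4). Mmp12 (SD 0.35) and Ctsd (SD 0.25) are among the widest bars drawn, and the 10 genes named for their largest SD are not drawn.

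After adjustment, no gene list varied detectably more between cultures than random lists of the same size and level. Of 18 lists tested, 0 passed in a one-sided permutation test with Benjamini-Hochberg adjustment, and 2 had an unadjusted p under 0.05. Macrophage identity genes had a median SD of 0.116 against 0.0791 in matched lists (permutation p = 0.0121, adjusted p = 0.218). Reference genes had a median SD of 0.105 against 0.0712 (permutation p = 0.0342, adjusted p = 0.259), and matching on the nearest genes in level, chosen after seeing the data, gave a permutation p of 0.312 for them and of 0.0310 for macrophage identity. Scaled to the 75th percentile of all spots, also chosen afterwards, the permutation p was 0.339 for reference genes and 0.0327 for macrophage identity. With quantile normalization the permutation p was 0.181 and 0.0533. With simulated spread in the cell cycle list of 20 members, the test recovered it at 2 times the SD in 16 of 20 runs and at 1.5 times in 6 of 20 runs. Lists of other sizes and shifts shared between genes were not simulated.

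Differences between arrays were larger than spot noise for many probes printed several times per array. With 1 array per culture, the test cannot part cultures from labelling, scaling or other effects of the array. In limma's moderated F test with Benjamini-Hochberg adjustment, 746 of 1742 such probes differed between arrays, none by over 2-fold. Among probes printed 10 times, 682 of 1038 differed, against 64 of 704 printed 2 times. The median largest difference between arrays was 0.164 in the former and 0.160 in the latter. These shares therefore do not show that probes printed 10 times varied more. Listed genes had 48 probes printed 10 times, of which 32 differed. The 4 of these with a difference over 0.5 belonged to Ctsd, Txn1, Lgals3 and Lyz2, named after their values were seen. Their largest differences between arrays were 0.59 for Ctsd (limma adjusted p = 8.12e-14), 0.58 for Txn1 (limma adjusted p = 4.43e-20), 0.69 for Lgals3 (limma adjusted p = 5.10e-18) and 0.71 for 1 probe of Lyz2 (limma adjusted p = 8.02e-07), whose other probe printed 10 times differed by 0.22. Each of the 4 probes was lower on replicates 2 and 3 than on replicates 1 and 4. This direction was not particular to them. The 100 brightest genes were higher on replicates 1 and 4 by a median of 0.251, against -0.002 over all detected genes. From median signals with normexp correction, 222 probes differed.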

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

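The noise test of the first pattern, the nearest-level matching of the second and the tests on 7 genes of the third were chosen only after the result was seen. Single arrays were set against the other 3 by Dixon's ratio at its 95% critical value in 89 series, of which 13 passed. These include the 10 genes chosen for their largest SD, and without them 9 of 79 series passed, where chance alone gives about 3.95.

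Replicate 1 had 26 genes over 2-fold higher than the mean of the other arrays, whose own counts were 4 to 6. Tsks was at -2.72 on replicate 1 against -5.99 to -5.75 elsewhere, and Gpr162 at -3.35 against -5.74 to -5.58. Position argued against a blemish joining spots of the 26 genes, since 0% of their 27 spots (exact 95% upper limit 12.8%) had another such spot within 5 rows and columns. However, 38 detected probes without a symbol were also over 2-fold higher on replicate 1, against 3 to 6 on the others. Their spots were not counted as neighbours, so a blemish reaching them, or confined to single spots, stays open. Signal that does not depend on transcripts stays open. On replicate 1, 5.24% of 1165 olfactory receptor probes were well above background (95% interval 4.03% to 6.68%). This was below the 5.41% to 6.95% on the others, but by less than its interval. The 45 detected on all arrays were higher there by a median of 0.28 (0.21 to 0.39), 1 of them by over 2-fold. The median was 1.23 in the 26 genes, which were picked for exceeding 1. The lowest detected level was highest on replicate 1 (-6.81 against -7.49 to -6.89). Requiring detection there favours probes that are higher on it, so the shift of the 45 probes decides nothing. For noise near the detection floor, 3013 genes of similar mean level were taken without the detection filter. On replicate 1, 5 were lower for 33 higher, a ratio of 0.152 (95% interval 0.0462 to 0.391). Replicates 2, 3 and 4 had 11 lower for 8 higher, 5 for 13 and 7 for 11. The interval lay under the ratio set for noise that goes both ways, and reached above the bound set for counting against noise. However, the 3013 genes were taken over the level range of the 26. Genes picked for being higher on replicate 1 were therefore counted again among the 33, which lowers the ratio. The test cannot decide, and noise stays open. No biological explanation was tested.

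Under the main scaling, reference genes spread more than lists matched in 20 level bins before adjustment (permutation p = 0.0342). The permutation p was 0.339 with the 75th percentile of all spots and 0.181 with quantile normalization, so this pattern depended on the scaling. Under the main scaling these genes were higher by 0.12 on the dimmer replicates 1 and 4 than on the brighter replicates 2 and 3. Compression of bright spots on the brighter arrays was first tested against lists matched in those bins, and the difference lay outside their central range of -0.03 to 0.09 (two-sided permutation p = 0.0130), which by the bound set beforehand counted against it. That bound was wrong because the highest bin was too wide: it ran from 3.10 to 7.36, its brighter genes differed by 0.12 more than its dimmer ones (95% interval 0.09 to 0.16), and all 8 reference genes in it were among the brighter. Matched instead on the 50 nearest genes in level, a choice made after the first p was known, the difference lay within the range of 0.02 to 0.20 (two-sided permutation p = 0.457). Such matching takes up any shift that genes of similar level share, whatever its cause. It therefore cannot part compression from another shared shift, and compression stays open. A single unusual array also remains possible, since the unadjusted p rose to 0.187 without replicate 1 and stayed under 0.05 without each other array, and no biological explanation was tested.

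Replicate 2 had 11 genes over 2-fold lower than the mean of the others, among them Keap1 at -4.59 against -2.80 to -2.72, but 4 of the 11 were also among the genes higher on replicate 1, which raises that mean. A blemish reaching the surrounding spots of most of these genes was argued against by the 77 neighbouring spots, whose median deviation was -0.0698 (95% interval -0.109 to -0.0325), and by the 47 neighbours of the remaining 7 genes, at -0.118 (-0.231 to -0.0688). The neighbours were pooled over genes, so a blemish around single genes, Keap1 among them, stays open. Uneven signal within the spots was checked with a log2 ratio. It set the median spot signal less its local background against the deposited background-subtracted signal. For the 11 genes this ratio shifted by 0.203 (0.0491 to 0.375). For the remaining 7 genes the shift was 0.0707 (-0.0338 to 0.203), inside a bound of 0.25. That bound had been set beforehand for all 11 genes and was applied to these 7 only afterwards. Background was subtracted separately in the numerator and the denominator, so the shift may also come from background. The check therefore cannot decide, and uneven signal stays open for all 11 genes. All 11 genes rested on 1 detected probe, and no biological explanation was tested.

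The other series with 1 array far from the rest were as follows. Il1b was at 1.32 on replicate 2 against 1.18 to 1.19. Nlrp3 was at -4.17 on replicate 1 against -4.29 to -4.28. Casp1 was at -2.92 on replicate 4 against -3.33 to -3.27, and Hmox1 was at 3.32 on replicate 4 against 3.21 to 3.23. Tlr4 was at -3.58 on replicate 2 against -3.36 to -3.35, and Isg15 was at -2.53 on replicate 2 against -2.20 to -2.15. Zfp3 was at -4.03 on replicate 2 against -5.86 to -5.69. The median deviation of the antioxidant list was 0.0771 on replicate 4 against -0.0362 to -0.0218, and that of the p53 list was 0.0256 on replicate 4 against -0.0095 to -0.0058.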

How the results depend on the processing

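Scaling to the 75th percentile of all spots and nearest-level matching were chosen after seeing the data. Counts of detected genes (8686 to 10158) and of listed genes (275 to 307) stayed within 1.5 times the reported ones. With the looser flag, detected members rose from 3 to 7 for lung epithelium, 1 to 4 for fibroblast and smooth muscle and 2 to 4 for mast cell and erythroid markers. No list passed the permutation test under any setting, with 1 to 4 at an unadjusted p under 0.05. The median SD was 0.108 with the looser detection flag, 0.244 with no filter on dim probes, 0.104 with the 75th percentile of all spots and 0.0797 to 0.0948 when each replicate was left out. Genes spanning over 2-fold numbered 21 from median signals with normexp, 777 with the looser flag, 163 with detection on at least 3 arrays, 2485 with no filter and 44 to 93 without each replicate, lowest without replicate 1 (44) and next without replicate 2 (64). Replicated probes differing between arrays numbered 222 from median signals with normexp, where the median spot SD was 0.161 against 0.0856, and 525 to 694 without each replicate. The cause was not tested. Centring on the median and the 75th percentile of all spots shift the zero point of every level. Under the other 8 settings that recomputed levels, 91 of 504 levels of named genes moved by over 1 SD, 48 of them among the 63 from median signals with normexp, where dim genes such as Fos (-4.35) and Cdh5 (-4.17) were higher. The offset of 50 added there is close to the mean processed signals of Fos (49.4) and Cdh5 (49.8). It raises dim genes and narrows their fold differences. The brightest probe in place of the mean moved 8 levels, turning the sign for Tnf (1.87), Cd36 (1.58) and Cdkn1a (1.62). No paired analysis was possible because the samples form 1 group. Dim genes are limited by signal over background, since admitting dimmer probes raised the spread.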

Other observations

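In all, 6 further lists were chosen after the main results were seen, and 12 of their genes, such as C1qa, Itgam, Gapdh, Hmox1 and Nqo1, also belong to the main lists. A list of class II and antigen presentation genes had 8 of 15 members above background, of which Tap1, Tap2, Psmb8 and Psmb9 serve class I presentation. Of the class II chains, RT1-Bb was at -6.41 ± 0.41 and RT1-Db1 at -4.36 ± 0.14, and RT1-Ba and RT1-Da were not well above background. The peptide exchange genes RT1-DMa (2.59 ± 0.05, n = 4) and RT1-DMb (2.17 ± 0.03) and the immunoproteasome genes Psmb8 (3.57 ± 0.08) and Psmb9 (2.64 ± 0.05) were detected. Cd74, the class II regulator gene Ciita and the costimulatory genes Cd40, Cd80 and Cd86 were not well above background on any array. In the complement list 9 of 14 members were detected, with properdin (Cfp) at 2.68 ± 0.03 and C2 at 0.76 ± 0.08, whereas C1qa, C1qb, C1qc, C1r and C1s were not well above background.

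Glycolysis genes were detected for 14 of 16 members, and iron handling genes for 12 of 13, with the iron exporter gene Slc40a1 not well above background. Eicosanoid genes were detected for 6 of 13 members, among them Alox5 at 3.57 ± 0.06 and Lta4h at 3.71 ± 0.02, while Alox15 and Ltc4s were not well above background. Of 9 measured targets and partners of the aryl hydrocarbon receptor 3 were detected, and Ahr, Cyp1a1 and Cyp1b1 were not well above background. Of the 5 further lists tested for spread 0 passed the permutation test after adjustment, and 1 had an unadjusted p under 0.05 (complement, permutation p = 0.0333, adjusted p = 0.166).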
